A study of Mus musculus with 12 samples.

How the data were processed

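The series holds 12 samples of cells from mouse peritoneal ascites in 4 groups of 3, profiled with a NanoString immune panel of 770 genes per the labels' design text. A table of 750 genes was analysed here, and all 12 of its columns matched a sample. Its values are log2 values normalized by the authors, and the software, background handling and reference genes behind them are not given in the sources used here. Within each sample, 2 raised to the value was a whole number times a single factor for 100% of genes, with a tolerance of 0.01, so counts and factors were recovered from the deposited log2 values. No replicate pair agreed within sampling noise: chi-square per degree of freedom over genes ran from 8.35 to 59.6. Samples were grouped by their titles. The genotype field of the 3 vehicle samples says FAKKD where their titles say FAKWT, and a control of untreated FAKWT samples was run as an alternative.

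Gene symbols follow the table. Of 750 symbols, 736 matched a current one in a RefSeq gene table of assembly GRCm38.p6, 8 matched through a synonym and 6 matched nothing. No genomic positions are given.

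Tests used limma 3.58.1 in R 4.3.3. A linear model with 4 group means was fitted to all 12 samples (lmFit, contrasts.fit, eBayes with trend), with two-sided moderated tests and Benjamini-Hochberg adjustment over 750 genes at 0.05 in each of 4 contrasts: FAKKD minus FAKWT, inhibitor minus vehicle, vehicle minus untreated FAKWT, and the difference between the first and second. The deposited values were tested as they are, with no filter and no pseudocount. Errors of log2 fold changes are moderated standard errors, and errors of group means are SDs. With 3 against 3 samples an exact permutation test cannot give a two-sided p under 0.1. Because the samples' factors differ between groups, each contrast was also fitted after shifting every sample to a common panel median, here called relative to the panel. Values that count molecules carry counting error, which is largest for the 148 genes with a mean recovered count under 20.

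Fixed before the data were examined were 24 gene lists for pathways and cell types, of which 23 had at least 3 measured members. The housekeeping list had 0 measured members and gave no result. In all 369 genes were on a list and 26 on several. Lists were tested with camera against the rest of the panel, with a preset correlation of 0.01 and, as an alternative, an estimated one, adjusted over 23 lists. Counts adjusted over the list alone are given beside those over all genes where they differ for a list that passed. Also fixed then was the rule for named genes: in each main comparison all measured CD155-TIGIT genes, the 10 highest and 10 lowest log2 fold changes among called genes whose samples do not overlap, and up to 3 members with the smallest p of each list described, and for the other contrasts the 5 highest and 5 lowest called genes. Some genes that the rule picks are not reported here by name, and they remain in every test and count of a list. Ccr2, Angpt1 and Klra7, which were near the floor in FAKWT samples, were given by counts. Outside that rule, genes of 1 comparison are repeated with their values in another (Pvr, Pvrl2, Epcam and the genes of the difference), and Lyz2, Ms4a1 in FAKKD and the genes drawn in panels were picked after their values were seen.

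On simulated data with changes of 0.5 and 1 log2 units in 100 genes each, drawn from the real means and factors of 750 genes, the FAKKD step recovered 27% and 57% with 3.45% false calls, and the inhibitor step 37% and 70% with 6.14%. A T-cell list shifted by 1 was found in both, and 0 lists without a shared member were called. Genes were simulated independently, while in the real data the estimated correlation within a list reached 0.61 (MHC class I). The simulation therefore cannot show how often lists of correlated genes are falsely called.

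Alternatives were panel median scaling, quantile normalization, a filter dropping the 25% of genes with the lowest mean, eBayes without trend or robust, array weights, fits with only the compared groups, thresholds of 0.1 or unadjusted 0.05, other controls, and leaving out each sample. Scaling to the total of recovered counts, a filter at a mean recovered count of 20, list tests with an estimated correlation after panel median scaling, and the list tests on the difference contrast were added after seeing the data. Planned pseudocount alternatives did not apply, since the values are already log2, and rescaling to housekeeping genes could not be run because none of that list was measured here. Figures were drawn with matplotlib 3.10.9.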

Results

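Expression of immune genes was measured with a NanoString panel, an assay in which colour-coded probes count single RNA molecules, in cells recovered from the peritoneal ascites of mice carrying ovarian tumour cells. The tumour cells either had wild-type focal adhesion kinase (FAK), a tyrosine kinase of cell adhesion sites, or were labelled FAKKD, an abbreviation the labels do not expand. Tumour cells had been injected into the peritoneal cavity, ascites was taken on day 21, and RNA came from its cells, a mixture of tumour and host cells. The 12 samples fell into 4 groups of 3: untreated FAKWT, untreated FAKKD, FAKWT with a FAK inhibitor (VS4716, 100 mg per kg by gavage), and FAKWT with vehicle. The 3 vehicle samples carry FAKWT in their titles but FAKKD in their genotype field, and the titles were followed. The series title names tumour FAK, immunosuppression and the CD155/TIGIT axis, so the question was how the ascites cells differ when tumour FAK is altered or inhibited. Ptk2, the gene of FAK, was not among the 750 genes analysed here, so the labels could not be checked against it.

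The deposited log2 values resolved into whole counts times a factor for each sample, and the recovered counts summed to between 588778 and 760152 per sample. Group mean totals were 665661 in FAKWT, 688840 in vehicle, 705924 in inhibitor and 696986 in FAKKD samples. The factor was 0.753 ± 0.085 (SD, n = 3) in FAKWT and 0.788 ± 0.094 (SD, n = 3) in vehicle samples, against 1.17 ± 0.063 (SD, n = 3) with the inhibitor and 1.46 ± 0.19 (SD, n = 3) in FAKKD samples. The median gene was higher by a log2 fold change of 0.95 in FAKKD than in FAKWT and by 0.54 with the inhibitor than with vehicle, and each comparison is given both as deposited and relative to the panel, after setting every sample's median gene to the same value. Relative to the panel the median log2 fold change was not 0 but -0.10 in FAKKD and -0.20 with the inhibitor, with 46% and 39.3% of genes positive. Counts higher and lower on that scale therefore lean towards lower. In all, 148 genes had a mean recovered count under 20.

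**Figure D1:**
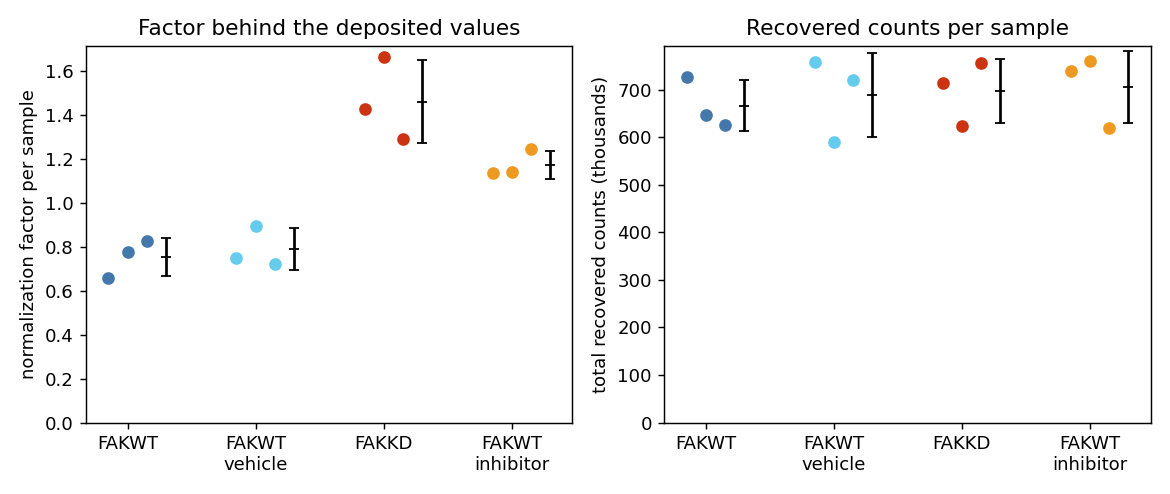
The left panel shows the factor behind the deposited values of each sample and the right panel the total recovered counts in units of 1000, by group, with points for samples and bars for the mean and SD of 3 samples. Factors ran from 0.659 to 0.896 in the FAKWT and vehicle samples and from 1.13 to 1.66 in the inhibitor and FAKKD samples, while the totals of the 4 groups overlapped.

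In ascites of mice with FAKKD tumour cells, the genes of epithelial and tumour cells fell and those of macrophages, B cells and MHC class II stood above the rest of the panel. With an estimated correlation only the epithelial and tumour list passed (adjusted p = 0.00425), though not after panel median scaling as well (adjusted p = 0.373), and the other 3 had an adjusted p = 0.858 each. The epithelial and tumour, macrophage and MHC class II lists also passed in the same direction between vehicle and untreated FAKWT samples (camera, adjusted p = 0.0034, 7.10e-04 and 3.26e-05). Their medians minus the panel's were -0.18, 0.20 and 0.69 there, and -1.94, 0.94 and 1.61 in FAKKD. Of 12 epithelial and tumour genes, 10 fell, 1 rose and 1 did not pass the test. Among them, the epithelial adhesion molecule Epcam had a log2 fold change of -1.70 ± 0.16 (SE, n = 3 and 3), the laminin-binding integrin subunit Itgb4 -1.75 ± 0.13 and mesothelin (Msln), a surface protein of mesothelium and ovarian tumours, -1.06 ± 0.10. Of 10 MHC class II genes 9 rose, with a median log2 fold change of 2.56 for the list. Those with the smallest p were the antigen-presenting chains H2-Aa (2.73 ± 0.24) and H2-Eb1 (2.68 ± 0.23) and Ciita (2.37 ± 0.18), the transactivator of the class. Pvr, which encodes CD155, the ligand of the inhibitory receptor TIGIT, fell by a log2 fold change of 1.19 (SE 0.12).

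The 4 measured genes of the CD155-TIGIT axis moved in different directions. Pvr went from a log2 value of 8.87 ± 0.08 in FAKWT to 7.68 ± 0.07 in FAKKD samples (SD, n = 3 each), with an adjusted p of 6.13e-06. Pvrl2, the gene of nectin-2, another TIGIT ligand, had a log2 fold change of -0.69 ± 0.08 (adjusted p = 1.83e-05). Relative to the panel, the changes of Pvr and Pvrl2 were -2.24 and -1.74. The epithelial and tumour list had a median log2 fold change of -0.99. In this mixture of cells, lower expression of Pvr and Pvrl2 cannot be told apart from a lower share of tumour cells. Tigit itself had a value of 0.14 ± 0.35 that did not pass (adjusted p = 0.737), and relative to the panel it was -0.92 (adjusted p = 0.0517). Cd96, a receptor for CD155, passed at 1.06 ± 0.40 (adjusted p = 0.0301), but its mean recovered counts of 15 in FAKWT and 15.7 in FAKKD samples were close, relative to the panel its change was 0.01, and it did not pass without FAKWT replicate 1, FAKWT replicate 3 or FAKKD replicate 4. As a list the axis stood below the panel with 1 gene higher and 2 lower (camera, adjusted p = 0.0317, and adjusted p = 0.483 with an estimated correlation). After panel median scaling the list did not pass (adjusted p = 0.199, in a range from 0.0151 to 0.215 over 9 scalings and sets of samples).

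Among cell-type lists, 19 of 22 macrophage and monocyte genes rose, 1 fell and 2 did not pass, and relative to the panel 13 were higher and 3 lower. Csf1r, the receptor for macrophage colony-stimulating factor, rose by 2.20 ± 0.12, the complement component C1qb by 2.17 ± 0.12 and Cd84 by 1.90 ± 0.09. The macrophage list stood above the panel (camera, adjusted p = 0.0317; adjusted p = 0.858 with an estimated correlation). The same held for MHC class II, with 9 of 10 genes higher on either scale (adjusted p = 0.0317; adjusted p = 0.858 with an estimated correlation). All 16 B-cell genes rose, 12 of them also relative to the panel, among them Cd37 (2.29 ± 0.17) and Btk, a kinase of B-cell receptor signalling (1.61 ± 0.12). The B-cell list passed narrowly (adjusted p = 0.0459; adjusted p = 0.858 with an estimated correlation) and no longer did without FAKWT replicate 2 (adjusted p = 0.082), FAKKD replicate 3 (0.055) or FAKKD replicate 5 (0.128), in a range from 7.14e-04 to 0.128 over the same 9. The epithelial and tumour list stood below the panel (adjusted p = 2.11e-11; adjusted p = 0.00425 with an estimated correlation). Of its 12 genes, 3 are also on another list.

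Most genes of the T-cell, dendritic, mast cell and MHC class I lists rose on the deposited scale, but these lists did not pass against the panel. After panel median scaling the T-cell list (adjusted p = 0.012) and the mast cell and eosinophil list (adjusted p = 0.0407) passed as higher, with adjusted p = 0.457 and adjusted p = 0.402 with an estimated correlation. Of 18 T-cell genes 17 rose, with Thy1 at 2.28 ± 0.30 and the T-cell receptor component Cd3d at 2.09 ± 0.29, and relative to the panel 11 were higher and 1 lower (camera, adjusted p = 0.193). For cytotoxic T and NK cells 16 of 21 genes rose, and relative to the panel 3 were higher and 2 lower (adjusted p = 0.492), and 11 of the 21 had low counts. For regulatory and helper T cells 15 of 19 rose (3 and 2 higher and lower relative to the panel, adjusted p = 0.44), for dendritic cells 11 of 15 (4 and 2, adjusted p = 0.513), for mast cells and eosinophils 8 of 11 (7 and 0, adjusted p = 0.44) and for MHC class I 11 of 14 (5 and 3, adjusted p = 0.44). Of 15 neutrophil genes 5 rose, 2 fell and 8 did not pass, and relative to the panel 1 was higher and 5 lower (adjusted p = 0.228), with the antimicrobial peptide gene Camp at 2.56 ± 0.24 and the myeloid receptor Trem1 at -1.42 ± 0.30.

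The single genes with the lowest fold changes included prostaglandin synthase Ptgs2 (-3.48 ± 0.32), the neutrophil chemokine Cxcl3 (-2.35 ± 0.49), the protease-activated receptor F2rl1 (-2.27 ± 0.18), osteopontin Spp1 (-2.20 ± 0.31), Anxa1 (-2.12 ± 0.11), the interleukin-1 receptor antagonist Il1rn (-1.87 ± 0.09), Tnfrsf12a (-1.80 ± 0.12) and Dusp4 (-1.70 ± 0.41). At the other end stood the interferon-induced GTPase Gbp2b (3.91 ± 0.62), the chemokine receptor Ccr9 (3.48 ± 0.32), the costimulatory receptor Cd40 (3.24 ± 0.17), the scavenger receptor Cd36 (3.18 ± 0.37), the fractalkine receptor Cx3cr1 (3.17 ± 0.41) and Cmah (3.16 ± 0.19). CD209e had 3.99 ± 1.43, which rests on single samples, with recovered counts of 19, 11 and 1 in FAKWT and 24, 16 and 303 in FAKKD. It did not pass relative to the panel (adjusted p = 0.0875), without FAKKD replicate 5 (2.76) or without FAKWT replicate 3 (2.78), nor against untreated and vehicle samples together (1.99). Ccr2, Angpt1 and Klra7 were counted near the floor in FAKWT samples, with mean recovered counts of 3.33, 2.33 and 3 there against 38.3, 16 and 19.3 in FAKKD samples. Of 18 other checkpoint genes 13 rose and 1 fell, with Cd86 at 2.16 ± 0.19, and of 19 suppressive mediators 12 rose and 2 fell, with the oxidase subunit Cybb at 2.21 ± 0.12. The balance turned relative to the panel, with 3 and 4 higher and lower for checkpoint genes and 5 and 10 for suppressive mediators.

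For the other lists the camera test did not pass. Of 31 interferon response genes 23 rose and 2 fell, of 27 cytokine and chemokine genes 13 rose and 2 fell, of 27 complement genes 15 rose and 2 fell, and of 18 stromal and endothelial genes 10 rose and 3 fell. Relative to the panel these were 5 and 9, 6 and 9, 9 and 5 and 7 and 5 higher and lower, so the first and second lists turned. Of 24 NF-kB and TNF signalling genes 13 rose and 3 fell, but relative to the panel 0 were higher and 20 lower, and the list passed as lower after panel median scaling (adjusted p = 4.27e-05; adjusted p = 0.457 with an estimated correlation). Of 27 adhesion genes 19 rose and 3 fell, of 20 lymphoid organisation genes 15 rose and 2 fell, of 5 proliferation genes 3 rose and 2 fell, and of 3 platelet genes 1 rose and 1 fell, against 5 and 11, 6 and 7, 1 and 3 and 1 and 1 relative to the panel, so all but the platelet list turned. The medians of the interferon, stromal and lymphoid organisation lists lay above the panel's while the test pointed below it. Adjusted over the list alone, 17 of the 23 lists kept both counts, and 10 rather than 9 MHC class II genes were higher and 11 rather than 10 epithelial and tumour genes lower.

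In limma, 559 of 750 genes passed an adjusted p of 0.05, 488 higher and 71 lower in FAKKD, and relative to the panel 436 passed, 177 higher and 259 lower. On both scales and in 1 direction 248 passed, 177 higher and 71 lower, while 81 passed in opposite directions. On the deposited scale the 3 and 3 samples did not overlap for 576 genes (76.8%), where chance gives 10%. The factors did not overlap either, with at most 0.825 in FAKWT and at least 1.29 in FAKKD samples. The factor by itself can therefore separate the samples of a gene, and overlap was not counted relative to the panel. The labels do not say that the 3 samples of a group came from separate mice, so p-values measure the spread between these samples.

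**Figure D2:**
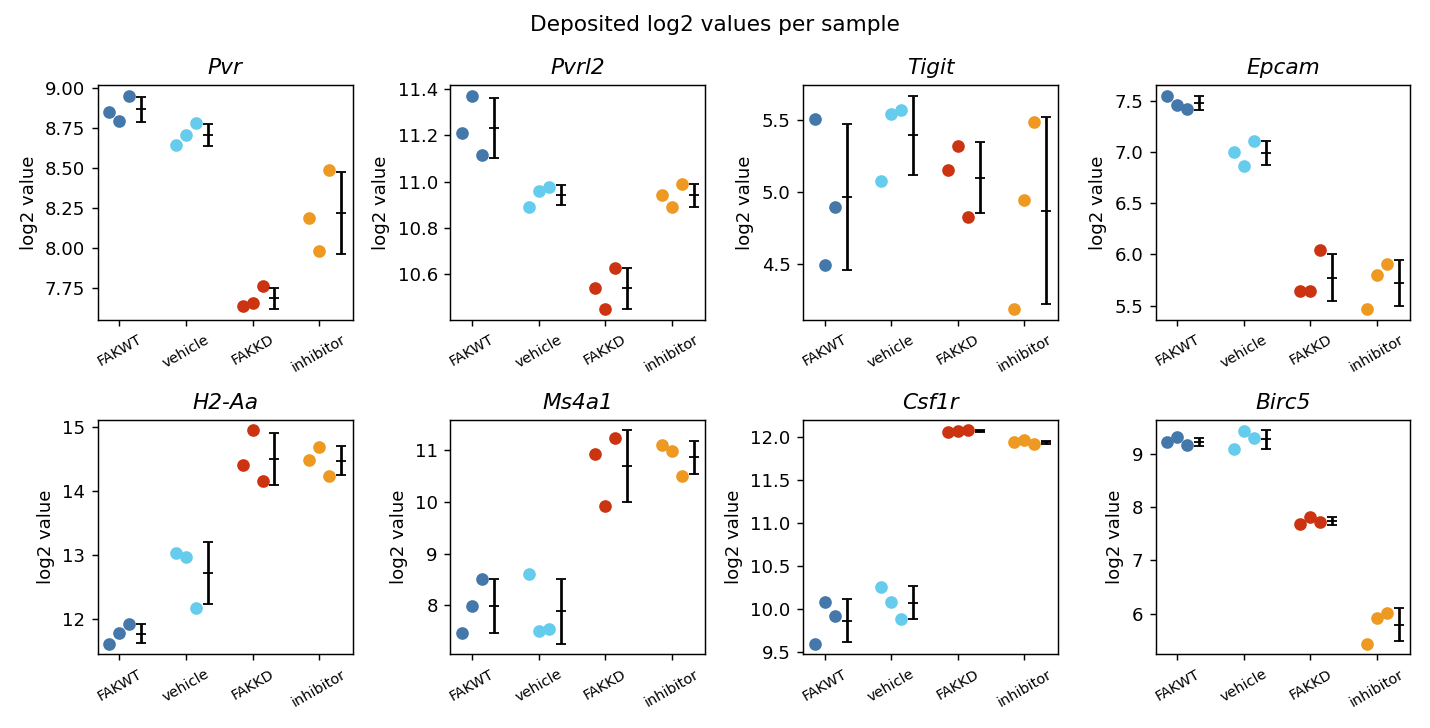
Deposited log2 values of 8 genes in each sample, by group, with points for samples, bars for the mean and SD of 3 samples, and axes that do not start at 0. In FAKKD against FAKWT samples Pvr (-1.19) and Epcam (-1.70) were lower and H2-Aa (2.73; 1.68 relative to the panel) and Ms4a1 (2.70; 1.64) higher, and Birc5 was lowest with the inhibitor (5.79 ± 0.31, SD).

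With the FAK inhibitor, compared with vehicle, interferon response, epithelial and proliferation genes were lower than the rest of the panel and B-cell genes higher. With an estimated correlation only the epithelial and tumour list passed (adjusted p = 0.0477), though not after panel median scaling as well (0.413), against 0.813 for interferon response, 0.324 for proliferation and 0.813 for B cells, and 4 of 10 splits of the 6 samples gave at least 4 lists, the real split included. The survivin gene Birc5, active in dividing cells, fell most, with a log2 fold change of -3.49 ± 0.15 (SE, n = 3 and 3). Arginase Arg1 (-2.49 ± 0.32), the chitinase-like Chil3 (-3.46 ± 0.81) and the checkpoint receptor Pdcd1, which encodes PD-1 (-2.51 ± 0.31), fell as well. Chil3 had -2.28 against untreated FAKWT samples and -4.48 without inhibitor replicate 5. B-cell genes rose, with the CD20 gene Ms4a1 at 2.97 ± 0.39 and the B-cell receptor component Cd79b at 3.05 ± 0.42, and so did Cxcl13 (3.38 ± 0.56), a chemokine that attracts B cells through Cxcr5 (3.04 ± 0.35).

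Pvr fell by 0.49 on the log2 scale (SE 0.12; adjusted p = 0.00443), and relative to the panel its change was -1.23. The epithelial and tumour list had a median of -0.59, and here too lower Pvr expression cannot be told apart from a lower share of tumour cells. Pvrl2 had the same deposited level in both groups (-0.00 ± 0.08; adjusted p = 0.993) and was lower relative to the panel (-0.74; adjusted p = 3.26e-04). Tigit had -0.53 ± 0.35 (adjusted p = 0.209) and relative to the panel -1.27 (adjusted p = 0.0143), and Cd96 had 0.42 ± 0.40 without passing on either scale. The 4-gene axis did not stand apart from the panel (camera, adjusted p = 0.135).

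Of 31 interferon response genes 6 fell, 1 rose and 24 did not pass, and relative to the panel 18 were lower and 0 higher. The chemokine Cxcl10 had -2.62 ± 0.49, Oasl1 -1.46 ± 0.18 and the exonuclease Isg20 -0.60 ± 0.10. The list stood below the panel (camera, adjusted p = 8.63e-05; adjusted p = 0.813 with an estimated correlation). Of 12 epithelial and tumour genes 8 fell and 2 rose, with Spp1 at -2.82 ± 0.31, Itgb4 at -1.11 ± 0.13 and Epcam at -1.27 ± 0.16 but Msln at 0.85 ± 0.10 and 0.11 relative to the panel. This list passed with the preset correlation (adjusted p = 1.74e-05) and with an estimated one (adjusted p = 0.0477). Of 5 proliferation genes 2 fell, Birc5 and the transferrin receptor Tfrc (-0.95 ± 0.11), and 1 rose, and relative to the panel 0 were higher and 5 lower. The proliferation list passed at an adjusted p of 0.0449, and gave an adjusted p = 0.324 with an estimated correlation.

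Of 16 B-cell genes 14 rose, 8 of them also relative to the panel, where 1 was lower (camera, adjusted p = 0.0449; adjusted p = 0.813 with an estimated correlation). Tnfrsf13c, the receptor for the survival factor BAFF, had 2.16 ± 0.22 and Cd37 1.92 ± 0.17. The B-cell call was lost without inhibitor replicate 4 (adjusted p = 0.073), vehicle replicate 3 (0.052) or vehicle replicate 4 (0.058), in a range from 9.94e-04 to 0.0726 over 9 scalings and sets of samples. Of 10 MHC class II genes 8 rose, 7 of them relative to the panel, with H2-Dma at 2.20 ± 0.29, but the list did not pass (adjusted p = 0.096). Of 18 T-cell genes 17 rose, and relative to the panel 5 were higher and 1 lower (adjusted p = 0.192), with the receptor zeta chain Cd247 at 1.66 ± 0.26. Of 22 macrophage genes 14 rose (adjusted p = 0.126), with Csf1r at 1.86 ± 0.12, and relative to the panel 9 were higher and 7 lower. Of 11 mast cell and eosinophil genes 8 rose, 5 of them relative to the panel (adjusted p = 0.372), with the mast cell chymase Cma1 at 3.69 ± 0.64 and the IgE receptor chain Fcer1a at 3.16 ± 0.56. Vehicle samples were uneven in these genes, with recovered counts of 1091, 157 and 191 for Cma1 and 160, 44 and 41 for Fcer1a, and against untreated FAKWT samples the changes were 1.74 and 1.49.

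Further genes at the ends of the range were Cx3cr1 (3.31 ± 0.41), Cd36 (2.98 ± 0.37), the chemokine receptor Cxcr4 (2.93 ± 0.30) and the activation marker Cd69 (2.87 ± 0.26) among the higher, and F2rl1 (-2.92 ± 0.18), Dusp4 (-2.63 ± 0.41), Ptgs2 (-2.36 ± 0.32) and Anxa1 (-2.16 ± 0.11) among the lower. Of 18 other checkpoint genes 11 rose and 3 fell, with Ctla4 at 1.28 ± 0.13 and Cd160 at 2.54 ± 0.30. Of 19 suppressive mediators 9 rose and 4 fell, with Tgfb2 at 1.75 ± 0.13. In both lists the balance turned relative to the panel, to 5 and 6 and 3 and 6 higher and lower. On that scale the median log2 fold change over all genes was -0.20.

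After panel median scaling the lists of MHC class II (adjusted p = 0.00179), T cells (0.014) and mast cells and eosinophils (0.0231) passed as higher, and NF-kB and TNF signalling as lower (0.0188). With an estimated correlation none of these passed, with adjusted p = 0.413, 0.476, 0.413 and 0.632.

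None of the other lists passed on the deposited scale. For cytotoxic T and NK cells 6 of 21 genes rose, for regulatory and helper T cells 13 of 19, for dendritic cells 6 of 15 with 1 lower, and for MHC class I 5 of 14. Relative to the panel these were 1 and 3, 4 and 1, 4 and 3 and 0 and 5 higher and lower. Of 15 neutrophil genes 3 rose and 2 fell, of 20 lymphoid organisation genes 8 rose and 4 fell, of 27 cytokine and chemokine genes 7 rose and 5 fell, with Lif at -1.98 ± 0.18 and Ccl3 at 2.44 ± 0.34, and of 27 complement genes 13 rose and 1 fell. These lists had 1 and 4, 6 and 6, 3 and 9 and 8 and 1 relative to the panel, so neutrophils and cytokines turned. Of 18 stromal and endothelial genes 9 rose and 2 fell, with Pecam1 at 2.60 ± 0.23 and Vegfc at -1.93 ± 0.16, of 24 NF-kB and TNF signalling genes 14 rose and 2 fell, of 27 adhesion genes 12 rose and 4 fell, and of 3 platelet genes 1 rose and 1 fell. On the scale relative to the panel these were 4 and 4, 0 and 12, 4 and 13 and 1 and 1, so NF-kB and adhesion turned. The medians of the stromal, platelet, lymphoid organisation and dendritic lists lay above the panel's while the test pointed below, and the reverse held for NF-kB. Adjusted over the list alone, 16 of the 23 lists kept both counts, and 5 rather than 6 interferon genes were lower.

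In limma, 448 of 750 genes passed, 369 higher and 79 lower with the inhibitor, and relative to the panel 349 passed, 133 higher and 216 lower. On both scales and in 1 direction 212 passed, 133 higher and 79 lower, while 35 passed in opposite directions. On the deposited scale samples did not overlap for 502 genes (66.9%), where chance gives 10%. Factors were at most 0.896 with vehicle and at least 1.13 with the inhibitor, so the factor by itself can separate the samples here too.

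**Figure D3:**
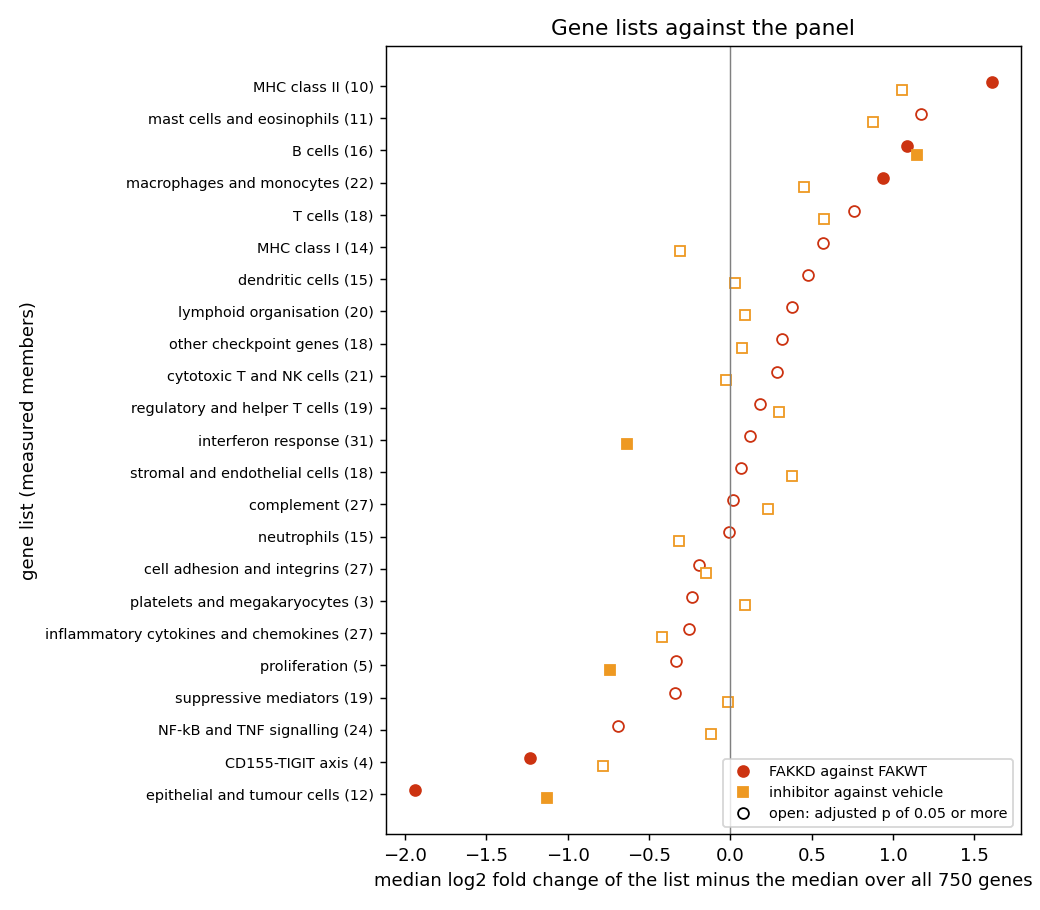
For each of 23 gene lists, the median log2 fold change minus the median over all 750 genes, for FAKKD against FAKWT (circles) and inhibitor against vehicle (squares), with filled symbols where camera passed an adjusted p of 0.05 with the preset correlation. The epithelial and tumour list lay lowest in both, at -1.94 and -1.13.

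Vehicle and untreated FAKWT samples were compared to look for changes of the ascites cells with gavage or handling. In limma 0 of 750 genes passed. An unadjusted p under 0.05 was found for 93, a larger share than the 0.05 that chance gives. Samples did not overlap for 121 genes (16.1%, where chance gives 10%). The absence of calls therefore does not show that the 2 control groups were alike. Pvr had -0.16 ± 0.12 and Epcam -0.49 ± 0.16, and neither passed. As lists, MHC class II stood above the panel in vehicle samples, with a median of 0.69 over the panel's (camera, adjusted p = 3.26e-05; adjusted p = 0.442 with an estimated correlation). The macrophage list (adjusted p = 7.10e-04; 0.442 with an estimated correlation) and the MHC class I list (adjusted p = 0.00411; 0.627 with an estimated correlation) were higher too. The epithelial and tumour list stood below the panel (adjusted p = 0.0034; 0.306 with an estimated correlation), as did NF-kB and TNF signalling and cell adhesion (adjusted p = 0.0328 each, and 0.627 with an estimated correlation). Over 9 scalings and sets of samples these lower calls were lost in 2 (epithelial and tumour, adjusted p up to 0.126), 4 (NF-kB and TNF signalling, up to 0.298) and 4 (cell adhesion, up to 0.0786). The other 17 lists did not pass, and of these the dendritic cell list (adjusted p = 0.0258) and the cytokine and chemokine list (adjusted p = 0.0464) passed as higher after panel median scaling, with adjusted p = 0.556 and adjusted p = 0.653 with an estimated correlation. Adjusted over the list alone, 7 of 10 MHC class II genes passed, where none did over all genes. Single genes passed in some alternatives, named here after their values were seen: H2-Aa, H2-Ab1, H2-Eb1 and Cd40 without vehicle replicate 9 (adjusted p = 0.0494), Ccr4 without FAKWT replicate 3 (0.0341) and Cxcl2 with only these groups fitted (0.0224).

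Across the 750 genes, the changes with the inhibitor and in FAKKD correlated with a Pearson r of 0.704 and a Spearman rho of 0.671. Genes are not independent replicates: over 100 pairs of splits of the samples the median size of r was 0.431, and pairs keeping neither real grouping reached 0.641. The comparisons share no samples. Signs matched for 85.2% of genes as deposited and 74.1% relative to the panel. Genes called in both numbered 320 higher, where independent lists would share 240, and 50 lower, where they would share 7.48, and 12 went in opposite directions. Relative to the panel, 97 were higher in both (31.4 for independent lists), 168 lower (74.6) and 18 opposite. Ptgs2, Spp1, F2rl1, Anxa1 and Dusp4 were among the 10 lowest in both comparisons and Cx3cr1 and Cd36 among the 10 highest.

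Tested directly, 179 of 750 genes changed differently with the inhibitor than in FAKKD, 57 more positively and 122 more negatively, and relative to the panel 195 did, 111 and 84. Msln (difference 1.92 ± 0.14) and the adhesion molecule Cdh1 (1.73 ± 0.40) fell in FAKKD and rose with the inhibitor as deposited, and relative to the panel the inhibitor values were 0.11 and 0.08. Il6, an inflammatory cytokine, rose by 2.11 ± 0.41 in FAKKD and fell with the inhibitor (-1.53 ± 0.41). Tdo2, a tryptophan-degrading enzyme, was 2.83-fold higher in FAKKD on the linear scale (a log2 fold change of 0.45 relative to the panel, not passing). With the inhibitor Tdo2 had a log2 fold change of -1.94 ± 0.26. Pvr fell further in FAKKD than with the inhibitor, by a difference of 0.69 ± 0.17 (adjusted p = 0.0136), and as deposited Pvrl2 fell in FAKKD only, with a difference of 0.69 ± 0.12 (adjusted p = 0.00232).

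**Figure D4:**
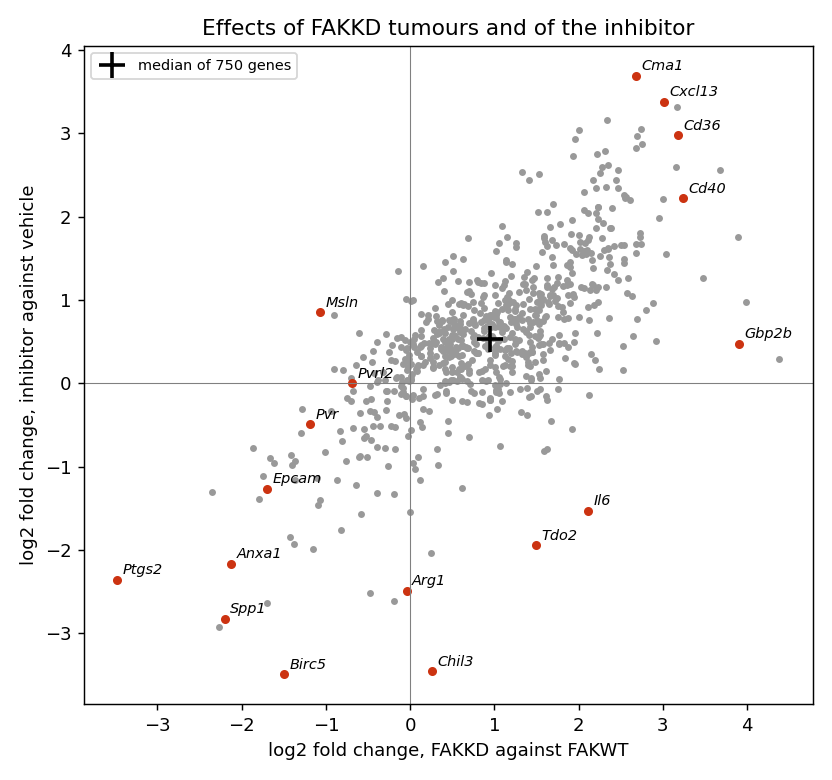
Log2 fold changes of the 750 genes for FAKKD against FAKWT (horizontal axis) and inhibitor against vehicle (vertical axis), each point a gene, with the cross at the median of each, 0.95 and 0.54. Most genes lie along the diagonal (r 0.704), and Il6 and Tdo2 lie in the lower right corner, higher in FAKKD and lower with the inhibitor as deposited.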

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

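Comparing the inhibitor effect with the FAKKD effect, 179 genes differed between the contrasts by the test of the difference itself. The genes with the most positive differences were Msln (1.92 ± 0.14), Cdh1 (1.73 ± 0.40), C1s1 (1.49 ± 0.23), Vegfa (1.22 ± 0.25) and Il1rn (1.10 ± 0.12), on the log2 scale with standard errors. The most negative were Chil3 (-3.72 ± 1.15), Il6 (-3.63 ± 0.58), Tdo2 (-3.44 ± 0.37), Gbp2b (-3.43 ± 0.88) and Ifi44 (-2.47 ± 0.57). All 10 kept their sign relative to the panel, where the values ran from -3.41 for Chil3 to 2.23 for Msln. In FAKKD and with the inhibitor, Il1rn had -1.87 ± 0.09 and -0.77 ± 0.09, Gbp2b 3.91 ± 0.62 and 0.47 ± 0.62, and Chil3 0.26 ± 0.81 and -3.46 ± 0.81. Chil3 was uneven between samples, with SDs of 1.82 in the inhibitor and 1.29 in the untreated FAKWT group (n = 3 each), and its difference did not pass in 8 of the 12 fits that left out 1 sample.

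Over the 100 pairs of splits of both sets of 6 samples, 4 gave at least 179 genes, the real pair included, a share under 0.05. The highest of the other pairs gave 372. The 3 other pairs that gave as many all kept 1 of the real groupings, so they hold that grouping's effect, and pairs that kept neither gave at most 0. In mixed groups the real effects add to the spread between samples, which lowers the count. These pairs regroup both comparisons, so they stand for the absence of both effects and not for equal effects. The share therefore cannot decide whether the inhibitor and FAKKD effects differ.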

How the results depend on the processing

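Scaling to total counts, the filter at 20 counts, the estimated correlation after scaling and the list tests on the difference were chosen after seeing the data. Counts of called genes stayed within 1.5 times in every other setting for FAKKD and the inhibitor, from 417 to 603 and from 327 to 504, but panel median scaling, quantile normalization and total count scaling moved the higher to lower split, from 488 and 71 to 177 and 259, 198 and 219, or 185 and 247 for FAKKD, and from 369 and 79 to 133 and 216, 177 and 150, or 157 and 177 for the inhibitor. For the difference, total count scaling gave 152 and 73. Vehicle against untreated FAKWT gave 1 gene (Cxcl2) with only the compared groups, 93 at an unadjusted p and 0 to 4 without 1 sample, and the difference 284 at an unadjusted p, which follows from the looser threshold. With an estimated correlation the lists passing fell to 1 for FAKKD, 1 for the inhibitor, 0 for vehicle and 0 for the difference, and with panel median scaling as well to 0 in all 4. For the inhibitor 8 lists passed with panel median scaling and 7 with quantile normalization. Without 1 sample, lists passing ranged from 4 to 5 for FAKKD, 3 to 6 for the inhibitor, 3 to 6 for vehicle and 4 to 6 for the difference, genes from 517 to 568, 400 to 440 and 139 to 209, and the correlation of effects from 0.659 to 0.732.

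Of 169 named values, scaling turned the sign of some that were called as deposited or after scaling. In FAKKD these were Irak4 (-0.0185) and Ikbkb (-0.18) with panel median scaling, Ikbkb (-0.14) with total count scaling, and Cd96 (-0.00153) and Tigit (-0.996) with quantile normalization. With the inhibitor they were Klrc2 (-0.0318), Tapbp (-0.24) and H2-M3 (-0.16) with panel median scaling, H2-M3 (-0.0110) with quantile normalization, and Tapbp (-0.12) and H2-M3 (-0.0305) with total count scaling. Values called on neither scale turned as well, such as Ppbp in both comparisons, Tigit in FAKKD and Cd96 with the inhibitor under panel median scaling. These settings remove most of the shift of the whole panel. Panel median scaling left medians of -0.10 in FAKKD and -0.20 with the inhibitor. No paired analysis was possible because the groups of each contrast share at most 1 replicate number, the difference contrast excepted. That contrast draws on all 4 groups, and pairing was not tested for it. Pseudocounts and housekeeping rescaling were not run. Counts limit the 148 genes under 20: of these 79 were called in FAKKD and 16 relative to the panel, and 27 and 9 with the inhibitor.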

Other observations

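The list tests on the difference contrast and the tests of the factor, of the low-count genes, of the leukocyte lists and of the vehicle labels were chosen after their results or related values had been seen. On the difference between inhibitor and FAKKD effects, 15 of 31 interferon response genes were more negative with the inhibitor and 1 more positive (20 and 1 adjusted over the list alone, 12 and 1 relative to the panel; camera, adjusted p = 0.00256; adjusted p = 0.792 with an estimated correlation). Gbp2b, an interferon-induced GTPase, rose by 3.91 ± 0.62 in FAKKD and had 0.47 ± 0.62 with the inhibitor, and Ifi44 had 1.92 ± 0.40 and -0.55 ± 0.40. Of 22 macrophage genes 11 were more negative and 1 more positive (13 and 1 over the list alone, 9 and 1 relative to the panel; adjusted p = 0.0223; 0.741 with an estimated correlation), and of 14 MHC class I genes 8 and 1 (9 and 1 over the list alone, 7 and 1 relative to the panel; adjusted p = 0.0236; 0.792 with an estimated correlation). Lyz2, a macrophage lysozyme, rose by 2.12 ± 0.16 in FAKKD and by 0.92 ± 0.16 with the inhibitor, where relative to the panel it was 0.18. The NF-kB list (3 of 24 more positive and 1 more negative, 2 and 1 over the list alone, 10 and 1 relative to the panel; adjusted p = 0.00368; 0.741 with an estimated correlation) and the epithelial and tumour list (adjusted p = 0.0236; 0.741 with an estimated correlation) were more positive with the inhibitor. The epithelial and tumour call was lost in 2 of 15 scalings and sets of samples (adjusted p up to 0.125), and the other 4 in 0. After panel median scaling the MHC class II list passed as more negative as well (adjusted p = 0.0213; 0.717 with an estimated correlation). The difference also holds the change of vehicle against untreated FAKWT samples with its sign reversed. There the macrophage, MHC class I, NF-kB, epithelial and tumour and MHC class II lists passed in the opposite direction. Their mean log2 fold changes there were 0.34, 0.41, -0.02, -0.15 and 0.64, against -0.79, -1.04, 0.10, 0.35 and -0.88 in the difference. How much of these calls rests on the controls was not tested. C1s1, a complement protease, had -0.14 ± 0.16 in FAKKD and 1.35 ± 0.16 with the inhibitor, and Vegfa -0.61 ± 0.18 and 0.61 ± 0.18. Relative to the panel these were -1.19 and 0.61 for C1s1 and -1.66 and -0.13 for Vegfa, whose inhibitor value turned.

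Most genes were higher on the deposited scale in FAKKD and with the inhibitor. This shift lay in the authors' normalization factor, by which the counts are multiplied. Mean log2 factors differed by 0.95 in FAKKD, against a median log2 fold change of 0.95, and by 0.58 with the inhibitor, against 0.54, while total recovered counts overlapped. After scaling to total recovered counts the medians were -0.065 and -0.079. Low counts multiplied by the factor were looked at as an explanation for part of the calls. The 148 low-count genes had a median change of 0.99 in FAKKD and 0.53 with the inhibitor. Any genes with unchanged counts take on the factor, so these medians cannot single out low counts. Of the 148, 79 and 27 were called, against 16 and 9 relative to the panel. That is a smaller share than the 559 and 448 called of all 750 genes. Whether the reference genes behind the factor themselves differed between groups was not tested, since none was analysed here. Whether the factor reflects a real rise of immune RNA per reference RNA stays open as well.

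Most B-cell, T-cell and macrophage genes rose (16 of 16, 17 of 18 and 19 of 22 in FAKKD, 14 of 16, 17 of 18 and 14 of 22 with the inhibitor) while most epithelial and tumour genes fell (10 and 8 of 12). Over the whole panel 488 of 750 genes rose in FAKKD and 369 with the inhibitor. Relative to the panel, these 3 leukocyte lists had 12 and 0, 11 and 1 and 13 and 3 genes higher and lower in FAKKD. With the inhibitor they had 8 and 1, 5 and 1 and 9 and 7. A lower share of tumour cells alone would raise all leukocyte genes alike only if tumour cells expressed none of them, which was not tested. The members of 7 leukocyte lists, counted in a single list and above 20 mean counts, moved apart in FAKKD (p = 0.00456, permutation test over genes, which are not independent) and with the inhibitor (p = 1e-05, the smallest that 100000 permutations can give). Genes also differed within a list, with an SD of 1.25 for neutrophils in FAKKD. The spread between lists therefore cannot decide about the share of tumour cells. In FAKKD the mean log2 fold changes as deposited were 2.02 for B cells, 1.67 for macrophages and 0.73 for neutrophils, and with the inhibitor 1.82, 1.03 and 0.25. The medians over all genes were 0.95 and 0.54, so the neutrophil means lay below the panel in both. A lower share of tumour cells, and a change in the make-up of the leukocytes or in their expression, remain open, and bulk values cannot separate these.

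Vehicle samples carry FAKKD in a genotype field. If they were FAKKD samples, few genes should differ from FAKKD, but 543 did (383 after panel median scaling), against 0 from untreated FAKWT on either scale. The values argue against mislabelled vehicle samples, while an effect of gavage was not tested apart from the comparison of vehicle with untreated samples.

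Other groupings of the 6 samples of each comparison make 10 splits, too few for a share under 0.05. In FAKKD against FAKWT 1 split gave as many as the real 559 genes, and the highest other gave 0. For the inhibitor 1 split gave as many as the real 448, and the highest other gave 0. For vehicle all 10 splits gave at least the real 0, and the highest other gave 1. For the list tests, 1 split gave as many as the real 5 lists in FAKKD (highest other 4), 4 splits gave as many as the real 4 with the inhibitor (highest other 5), and 1 gave as many as the real 6 with vehicle (highest other 4). The correlation of 0.704 between the effects was reached by 1 of 100 pairs of splits, the real pair, which is given as a description only. The highest other pair had 0.688, and pairs keeping neither real grouping reached 0.641.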
